A study of Homo sapiens with 2 samples.

How the data were processed

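Total RNA of H1299 cells from 2 cultures was hybridised to Agilent 1-colour (Cy3) arrays, 1 array for the culture without Dox and 1 for the culture with 1 µg/ml Dox for 48 h. Per the labels' protocols, RNA was isolated with TRIzol, column-purified, and amplified and labelled as cRNA with an Agilent Low Input Quick Amp kit. Groups were taken from the source names in the labels, which say with or without Dox; the treatment field of both samples carries the same Dox dose and time, and was read as the treatment of the Dox culture.

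The deposited scanner files hold spot intensity on a linear scale for 62976 spots in 384 rows and 164 columns, per the file headers. The same headers name Agilent Feature Extraction 10.7.1.1 and array design 072363, with probe coordinates on the human build hg19 (GRCh37). The submitters' processing notes name Agilent Feature Extraction 9.5.1.1, and the difference between these versions was not resolved. The processed intensity is background-subtracted and detrended within each array, per the file headers, and is not normalized between arrays. The authors' value table holds linear intensity with 1 row per probe. Its 2 columns had the same median of 8.47 and, once sorted, differed by at most 6.50 at any rank, so it was read as quantile-normalized. Its log2 differences correlated with those computed here at 0.996 across probes, and with a quantile normalization of the scanner files at 0.9999, which settled its scale and direction.

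Control spots were left out, as were 73 gene spots flagged as outliers on the array without Dox and 117 on the array with Dox. No spot was saturated. The remaining spots covered 58201 probes, and spots of the same probe were averaged on the log2 scale. Since under 50% of the probes were well above background on both arrays, each array was scaled by the 75th percentile of the 25678 probes that were, which was 1729 without Dox and 1490 with Dox. Log2 processed signal minus log2 of that percentile is the level used throughout, and the difference between the arrays is without Dox minus with Dox. This scaling removed an offset of 0.21. Readings printed for single probes and genes are signals before scaling, while differences and folds are after it. Scaling cannot show a global rise or loss of mRNA. The 7 spike-in probes well above background had a median scaled difference of −0.08, with a range from −0.11 to −0.0036.

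A gene's difference is the mean over its probes well above background on both arrays. Probe names were matched to gene symbols through a RefSeq gene table (assembly GRCh38.p14), used for names, gene types and genomic spans only. A symbol was found for 35016 probes, 31104 of them by accession, 48 by another accession, 3366 by symbol, 496 by an older symbol and 2 by description, and 23185 probes had none. The array held 23575 symbols, of which 14802 were measured on both arrays. Coordinates are those of the probes in the files, and exon or untranslated-region positions were not analysed here.

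With 1 array per condition there was no test, SE or p-value. Genes were counted at 2-fold, and precision was read from the repeated spots and from different probes of a gene. The lowest signal well above background was 11.0 without Dox and 9.73 with Dox. A gene well above background on 1 array only was given a lower bound, its signal on that array over the higher of 2 values on the other, the lowest signal well above background and its own signal.

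The design, the alternatives, the naming rule and 36 gene lists were fixed before the data were examined; older symbols in the lists were updated afterwards. The median difference of each list was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. A list's shift is its median minus that of all genes. Genes named in the text are SAMD4A, SAMD4B and the mRNAs reported as Smaug targets; the 12 highest and 12 lowest protein-coding genes with a full symbol, a mean signal at or above the 25th percentile and all probes in 1 direction; the 2 highest and 2 lowest members of each list; and the 3 largest bounds in each direction. Some genes that meet this rule are not reported here.

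Alternatives were normexp background correction with an offset of 50, quantile, median and loess normalization, no detection filter, a stricter one that kept probes at or above the median signal, the brightest probe of a gene, the authors' value table, and thresholds of 1.5-fold and 3-fold. After the data were seen, the 75th percentile over all probes and the removal of trends with probe GC content and with gene span were added. Runs of neighbouring genes were sought along the probe coordinates at 1.5-fold or more.

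The procedure was tested on simulated data for the 14802 genes of this comparison. With the noise of repeated spots and of different probes, 100% of 100 genes set to 3-fold were recovered at 2-fold, 0% of 100 genes set to 1.5-fold and 0 of 14584 unchanged genes passed. A list shift of 0.35 came back as 0.33, and 1 of 35 other lists stood apart. The noise was drawn at median SDs, 0.14 between probes, and 2-fold lay far outside it. The 2-fold results were therefore nearly fixed in advance. Such noise leaves out the variation between cultures and probes noisier than the median. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6; plots were drawn with matplotlib 3.10.9.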

Results

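RNA levels were measured in H1299, a human non-small-cell lung carcinoma line, on 2 Agilent arrays, 1 for each of 2 cultures. The cells had lost both SAMD4A and SAMD4B and carried a SAMD4A module that doxycycline (Dox) switches off. SAMD4A (Smaug1) and its paralog SAMD4B are RNA-binding proteins that recognise a stem-loop in target mRNAs, repress their translation and recruit the CCR4-NOT deadenylase to them. Dox is a tetracycline antibiotic that can also inhibit mitochondrial translation. The module was meant to be on in the culture without Dox, and off in the culture kept for 48 h with 1 µg/ml Dox. The comparison asks which transcripts differ with SAMD4A expression, and all differences are given as log2 signal without Dox minus log2 signal with Dox, so that positive values mark higher signal where SAMD4A was meant to be expressed.

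Of 58201 probes, 27165 (46.7%) were well above background without Dox and 26591 (45.7%) with Dox. On both arrays 25678 probes (44.1%) were well above background, and they measured 14802 genes. Each condition had 1 array and no biological replicate, so differences are described by their size and carry no test. The technical error could be read from 274 probes printed 10 times on each array. Their log2 difference had a median SD of 0.08 for a single spot, and 3 of 22422 spot pairs differed by 2-fold or more. Different probes of the same gene varied more, with a median SD of 0.14 over 4394 genes. The cultures differed in Dox as well as in the intended SAMD4A expression, and Dox-treated cells without the module were not analysed here.

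SAMD4A signal was higher in the culture without Dox. The gene had 4 probes on chromosome 14 (GRCh37). Readings here and below are before scaling, and differences and folds are after it. Probe A_33_P3264926 (55251276 to 55251335) read 1025 without Dox and 69.6 with Dox, a difference of 3.67 or 12.7-fold. Probe A_33_P3343503 (55034385 to 55034444) read 47.4 and 15.5, which was 2.64-fold higher without Dox. Probe A_24_P383523 (55255724 to 55255783) read 166 and 98.2, 1.46-fold higher, and probe A_33_P3344292 (55033854 to 55033913) was not well above background on either array. The mean over the 3 measured probes was 1.87, but their differences ran from 0.55 to 3.67. SAMD4B was lower without Dox at both of its probes on chromosome 19 (GRCh37), with a mean of −0.74. Probe A_24_P136758 (39874799 to 39874858) read 621 without and 1019 with Dox, 1.91-fold lower, and probe A_33_P3262717 (39870627 to 39870686) read 82.1 and 103, 1.46-fold lower. Where these probes lie relative to the expressed SAMD4A sequence or to the edited parts of either gene was not analysed here, and a probe outside them does not check the module or the knockout.

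**Figure D1:**
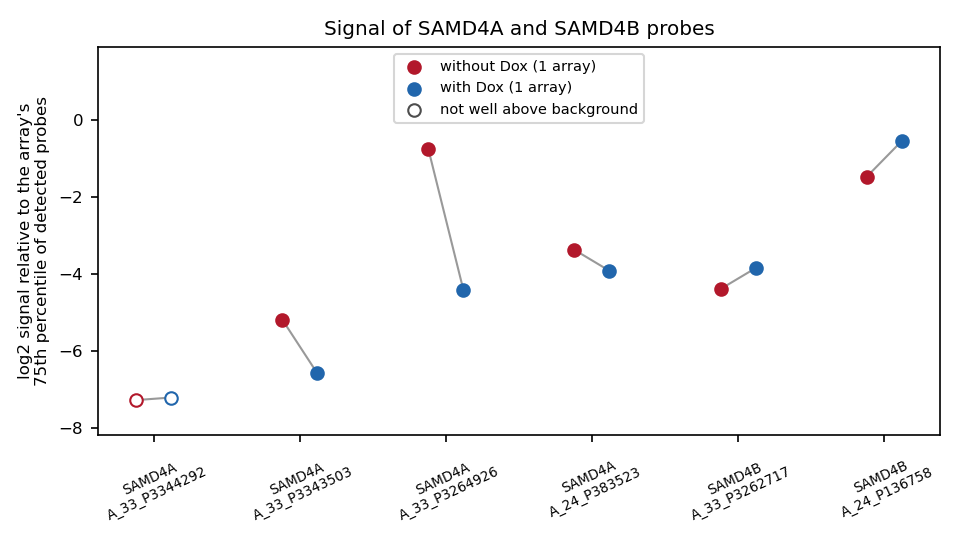
Log2 signal of each SAMD4A and SAMD4B probe on the array without Dox (red) and the array with Dox (blue), relative to the array's 75th percentile of detected probes; open circles were not well above background. SAMD4A probe A_33_P3264926 stood at −0.75 without Dox and −4.42 with Dox, while both SAMD4B probes were lower without Dox.

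Few genes differed strongly. Of the 14802 genes, 63 were at least 2-fold higher and 126 at least 2-fold lower without Dox, 1.28% in all, and 63.3% lay within 1.2-fold. Among 12912 protein-coding genes, 47 were at least 2-fold higher and 116 at least 2-fold lower. Of 4394 genes measured by several probes, 27 (0.61%) differed by 2-fold or more, 16 higher and 11 lower. The excess of lower genes thus lay among genes with 1 probe. In all 27 the probes of the gene pointed the same way, which a mean of that size makes likely. ANKRD1 and LINC00417 were at least 4-fold higher, and 2 genes, BIK among them, at least 4-fold lower. LINC00417, a long non-coding RNA at 2.13, was named after its value was seen. The 2-fold counts leaned on moderately dim genes: normexp background correction left 17 higher and 32 lower, and a filter keeping brighter probes left 18 and 35.

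ANKRD1, a muscle ankyrin-repeat protein, and CCN2, a matricellular growth factor, are both textbook YAP/TEAD targets. ANKRD1 signal was 4.92-fold higher without Dox (497 against 87.1), and CCN2 was 3.82-fold higher (1768 against 398). IGFBP3, an insulin-like growth factor binding protein, was 3.41-fold higher. ADM, which encodes the vasodilator peptide adrenomedullin, read 9621 without and 2630 with Dox, 3.15-fold higher. Also in this group were ZNF404 (1.42), PLCB4 (1.41), COL12A1 (1.36), ZNF45 (1.31), MAFF (1.19), GBX2 (1.19) and the kinase gene NUAK2 (1.17). ZNF404, PLCB4, COL12A1 and ZNF45 were each measured by 2 probes. ZNF404 and ZNF45 lie within a stretch of 6 neighbouring measured genes on chromosome 19 (GRCh37, 44326257 to 44471466) that were all at least 1.5-fold higher.

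BIK, which encodes a pro-apoptotic BH3-only protein, had the lowest difference of the named genes. It read 293 without and 1187 with Dox, 4.69-fold lower. The ciliary protein gene CYS1 was 3.71-fold lower and the collagen gene COL9A3 was 2.99-fold lower. RGS14 (−1.48), OSBPL5 (−1.44) and EEIG1 (−1.42) followed, EEIG1 being the brightest of this group at 3452 and 7942. The receptor genes PTGER1 for prostaglandin E2 and NTSR1 for neurotensin stood at −1.40 and −1.33. ASB2 (−1.34) and CACNG6 (−1.34) were similar. VGLL4, a TEAD-binding cofactor that competes with YAP, stood at −1.32, with −1.45 and −1.20 at its 2 probes.

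**Figure D2:**
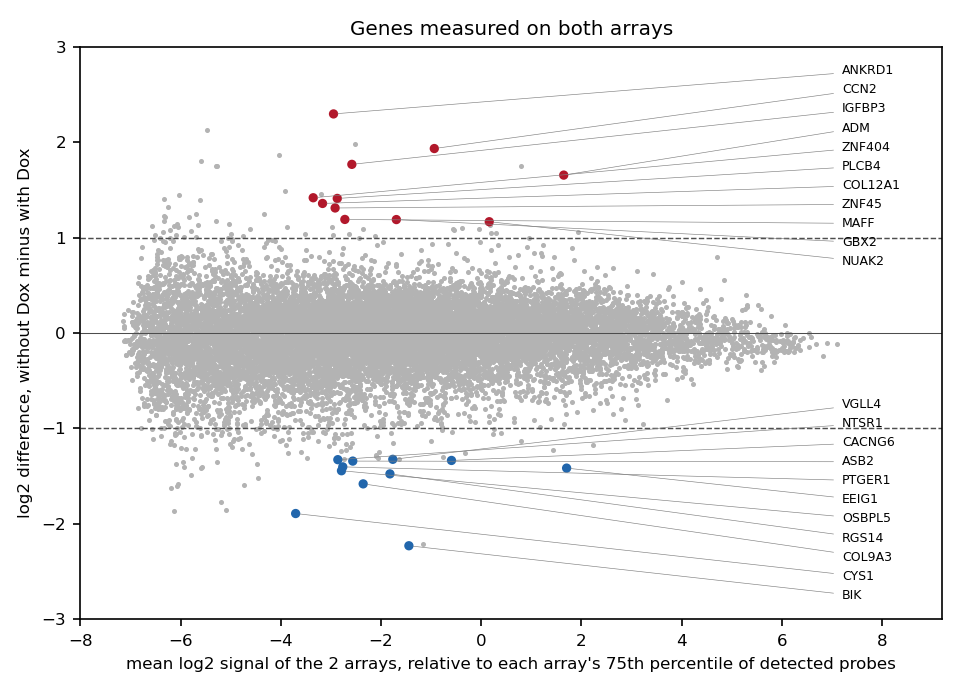
Log2 difference (without Dox minus with Dox) of each gene against its mean log2 signal relative to each array's 75th percentile of detected probes. Of the 14802 genes, Y-linked genes, XIST and TSIX were left out. Dashed lines mark 2-fold. Labels name protein-coding genes among the 12 highest (red) and 12 lowest (blue) by the rule for named genes, from ANKRD1 at 2.30 to BIK at −2.23.

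The mRNAs reported to be bound or regulated by Smaug proteins did not share a direction. Of 6 such mRNAs, 3 were higher and 3 lower, with a median of 0.03. ERRFI1, a feedback inhibitor of the EGF receptor, was lowest without Dox at −0.52. UQCRC1 of respiratory complex III stood at −0.17, and HSP90AA1 at −0.02, or 0.07 after quantile normalization. NANOS1 was at 0.08, SDHB of complex II at 0.17 and HSP90AB1 at 0.39. This median lay at percentile 76.1 of 10000 random lists of the same size matched on signal. The CCR4-NOT and mRNA decay list had a median of 0.06 over 37 genes (percentile 86.3), with 24 higher and 13 lower. Its extremes were ZFP36L2 (0.43) and CNOT9 (0.38) on the higher side, and the poly(A) nuclease subunits PAN3 (−0.62) and PAN2 (−0.41) on the lower side.

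Gene lists were compared with such random lists as a description of these 2 arrays. A list was said to stand apart when its median lay outside the middle 95% of the random lists. Of 36 lists, 5 stood apart on the higher and 10 on the lower side, where 1.8 would do so by chance. Members of a list are often regulated together, so the percentile is not a significance level.

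YAP/TEAD targets, which respond to Hippo signalling and cell contact, were higher without Dox. The median was 0.33 over 18 genes, above all 10000 random lists, and 15 were higher. At 1.2-fold or more, 11 were higher and none was lower. ANKRD1 (2.30), CCN2 (1.94) and NUAK2 (1.17) were at least 2-fold higher, while MYOF (−0.23) and TGFB2 (−0.04) were lowest.

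Ribosome biogenesis genes, whose products process and assemble ribosomal RNA in the nucleolus, were also higher without Dox. Their median was 0.33 over 28 genes, again above every random list. All but 1 were higher, and 19 were so by 1.2-fold or more. PPAN (0.70) and NOP16 (0.65) were highest, and the bright genes NPM1 (0.06) and FBL (−0.13) were lowest.

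Protein-quality genes had smaller shifts. Proteasome subunits had a median of 0.08 over 31 genes (percentile 99.7), with 24 higher, among them PSMD11 (0.47) and PSMD12 (0.43); PSMB3 stood at −0.12 and PSMB6 at −0.06. Cytosolic heat shock proteins had a median of 0.17 over 20 genes (percentile 99.9) but were mixed, with 11 higher and 9 lower. HSPB8 (0.75) and CHORDC1 (0.49) were at one end, CRYAB (−0.77) and HSPA1B (−0.21) at the other. Endoplasmic reticulum stress genes and chaperones did not stand apart, with a median of 0.09 over 21 genes (percentile 92.3). They ranged from EDEM1 (−0.67) and MANF (−0.32) to HSP90B1 (0.26) and DNAJB11 (0.29).

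Targets of ATF4, the transcription factor of the integrated stress response, had a median of 0.12 over 39 genes (percentile 99.2). Of these, 25 were higher and 14 lower. The cystine transporter gene SLC7A11 stood at 0.55, and ATF3 at 0.77 as the mean of 4 probes that disagreed, from −0.18 to 1.26. The stress-response genes NUPR1 (−1.32) and DDIT4 (−0.87) went the other way, NUPR1 being the list's only member at least 2-fold apart.

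**Figure D3:**
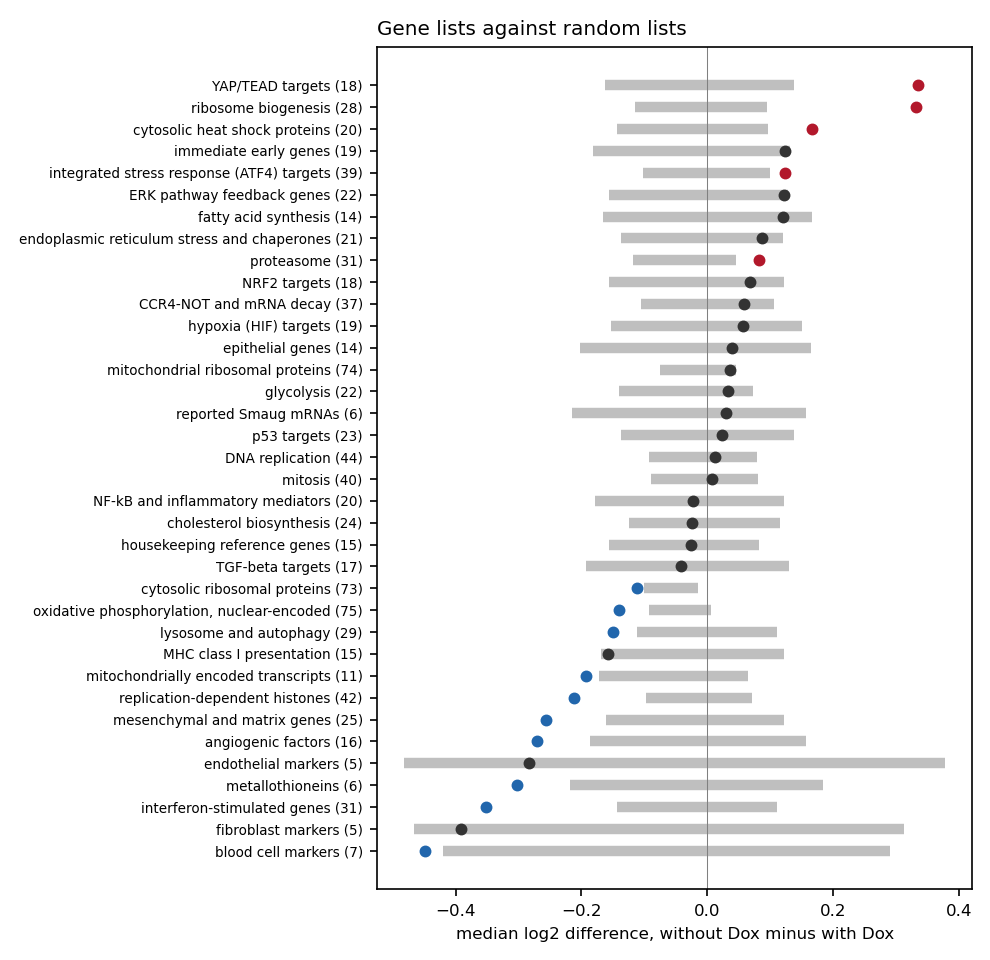
Median log2 difference (without Dox minus with Dox) of each of the 36 gene lists, with the number of measured genes in brackets; grey bars span the middle 95% of 10000 random lists matched on size and signal. Red lists lay above and blue lists below that range, from ribosome biogenesis and YAP/TEAD targets, each at 0.33, to interferon-stimulated genes at −0.35 and the dim blood cell markers at −0.45; black lists lay within it.

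Interferon-stimulated genes were lower without Dox as a group. The median was −0.35 over 31 measured genes, below all 10000 random lists. Of these, 29 were lower, 17 by 1.2-fold or more, and none was higher by 1.2-fold. SAMD9 (−0.92) and the exonuclease gene ISG20 (−0.79) were lowest; IFIT5 (0.12) and USP18 (0.05) were the 2 higher genes. With no filter on dim probes the list had 41 genes and a shift from all genes of −0.19 in place of −0.34, and still stood apart. Of the markers of other cell types, which were dim, blood cell markers had a median of −0.45 (percentile 1.66) and stood apart, but not after quantile normalization (percentile 3.23). Fibroblast (−0.39) and endothelial markers (−0.28) did not stand apart. The MHC class I presentation list, which interferon also induces, had 13 of 15 genes lower and a median of −0.16 at percentile 3.47, and it stood apart after quantile normalization (percentile 2.49), in the authors' value table and with the GC trend removed. The immunoproteasome gene PSMB9 (−0.61) and TAPBP (−0.31) were lowest, while NLRC5 (0.50) and TAP2 (0.33) were higher. NF-kB and inflammatory mediators had a median of −0.02 over 20 genes (percentile 51.4), from LTB (−0.91) and TNFAIP2 (−0.78) to NFKB1 (0.17) and BIRC3 (0.31).

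Respiratory chain transcripts were slightly lower without Dox than random lists of like signal. Nuclear-encoded genes of oxidative phosphorylation had a median of −0.14 over 75 genes, below every random list, and 62 were lower, but only 8 by 1.2-fold or more. Bright signals lay slightly below 0 as a class. The random lists matched to this list had a median of −0.05, and the brightest spike-in probe stood at −0.11 after scaling. Counts of genes below 0 therefore overstate the decrease in these bright lists. NDUFA1 (−0.36) of complex I and COX5B (−0.35) of complex IV were lowest, UQCRFS1 (0.25) and SDHB (0.17) highest. Mitochondrially encoded transcripts had a median of −0.19 over 11 genes (percentile 0.67), where matched random lists had −0.06. COX2 (−0.34) and ND3 (−0.29) were lowest, while ND1 (0.39) and ND6 (0.22) were higher. This list no longer stood apart after quantile normalization, where its shift from all genes was −0.09 in place of −0.18. Mitochondrial ribosomal proteins did not stand apart at a median of 0.04 over 74 genes (percentile 94.8), from MRPL23 (−0.33) and MRPL21 (−0.25) to MRPS25 (0.43) and MRPL33 (0.43). Their shift of 0.05 was 0.079 with the trend of probe GC content removed and 0.097 with that of gene span removed, and the list then stood apart. Cytosolic ribosomal proteins had a median of −0.11 over 73 genes (percentile 0.58), with 68 lower, where matched random lists had −0.06. Their shift of −0.10 became −0.02 after quantile normalization and then no longer stood apart. RPS29 (−0.36) and RPL36 (−0.31) were lowest, RPS4X (0.68) and RPL27A (0.29) highest. The RPS4X value averages probes at −0.03 and 1.39.

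Replication-dependent histone genes had a median of −0.21 over 42 genes, below every random list, with 37 lower and 14 of these by 1.2-fold or more. H2BC7 (−0.51) and H3C7 (−0.47) were lowest, H3C3 (0.21) and H3C11 (0.20) highest. Histone paralogs are close in sequence, so a probe can read several of them. How fully the labelling kit captures histone mRNAs was not tested, so these values describe signal and not transcript level. DNA replication genes showed no such shift, with a median of 0.01 over 44 genes (percentile 64.6). CDC25A (0.48) and CDC6 (0.38) were their highest members, LIG1 (−0.39) and CDT1 (−0.33) their lowest. Mitosis genes had a median of 0.01 over 40 genes (percentile 61.1), from PLK1 (−0.28) and UBE2C (−0.19) to ANLN (0.35) and CENPE (0.48).

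Lysosome and autophagy genes were lower without Dox, with a median of −0.15 over 29 genes (percentile 0.53) and 23 lower, 11 by 1.2-fold or more. The protease gene CTSB (−0.71) and the autophagy kinase gene ULK1 (−0.62) were lowest. ATG9A (0.41) and the cholesterol transporter gene NPC1 (0.27) were higher. With normexp the list's shift was −0.08 in place of −0.14, still apart.

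Mesenchymal and matrix genes had a median of −0.26 over 25 genes (percentile 0.055), and 18 were lower. The 4 members at least 2-fold lower were the matrix metalloproteinase genes MMP14 (−1.49), MMP1 (−1.31), MMP2 (−1.22) and MMP9 (−1.20), of which MMP2 and MMP9 were named after their values were seen. MMP14 was dim, at 18.6 without and 44.9 with Dox. THBS1 (1.09), which encodes thrombospondin 1, and the transcription factor gene SNAI1 (0.52) were higher. The angiogenic factor list had a median of −0.27 over 16 genes (percentile 0.29). Its members were not sorted into promoters and inhibitors of vessel growth. TIMP2 (−0.85) and ANG (−0.65) were lower, and THBS1, a member of both lists, and FGF2 (0.59) higher. Both lists depended on dim genes. With brighter probes alone, the matrix list's shift of −0.24 was −0.07 and no longer stood apart, and with no filter it was −0.03 but still stood apart. With brighter probes the shift of the angiogenic list turned from −0.26 to 0.24, and with no filter it was 0.0000 and did not stand apart.

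The list of metallothioneins, small metal-binding proteins, also holds SLC30A1, which is not one of them. It had a median of −0.30 over 6 genes (percentile 0.41), from MT1E (−0.45) and MT1B (−0.44) to MT1X (−0.05) and SLC30A1 (0.19). Without a filter on dim probes the list had 10 genes, a shift of −0.01 in place of −0.29, and did not stand apart. Its MT1 genes are close paralogs that probes may not separate.

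**Figure D4:**
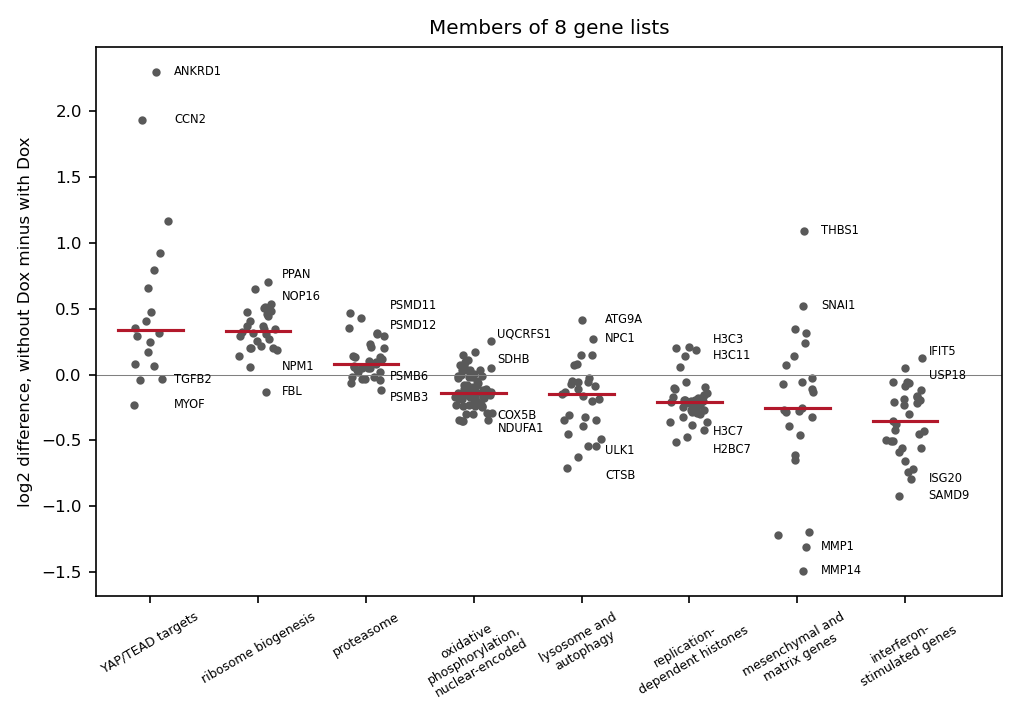
Log2 difference (without Dox minus with Dox) of each measured member of 8 lists that stood apart; each point is a gene, red lines are list medians, and the horizontal spread within a list carries no value. The medians run from 0.33 for YAP/TEAD targets to −0.35 for interferon-stimulated genes, and the labels give the 2 highest and 2 lowest members of each list.

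Immediate early genes had a median of 0.12 over 19 genes (percentile 96.9), with 15 higher. EGR1 was 2.02-fold and FOS 1.89-fold higher, while IER2 (−0.17) and ZFP36 (−0.14) were lowest. This list stood apart under 7 of the 9 other processing settings that can move a list's shift, with shifts up to 0.24 where the main one was 0.14. ERK pathway feedback genes had a median of 0.12 over 22 genes (percentile 96.9), from DUSP4 (−0.53) and ERRFI1 (−0.52) to EPHA2 (0.50) and HBEGF (0.74), and stood apart with the span trend removed (percentile 99.4). TGF-beta targets had a median of −0.04 over 17 genes (percentile 44.6), with CDKN2B at 0.36. COL4A2 (−0.52) and TGFBI (−0.48) were its lowest members.

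Some genes were well above background on 1 array only, so that their difference has a lower bound. There were 437 such genes without Dox, of which 53 were at least 2-fold higher by that bound, and 350 with Dox, of which 46 were at least 2-fold lower. After quantile normalization these counts were 41 and 66, so the balance between the directions depends on the scaling. MC5R, a melanocortin receptor gene, was at least 6.04-fold higher without Dox. EDN2, which encodes endothelin 2, was at least 3.84-fold higher and PRM3 at least 3.52-fold higher. In the other direction, the adenylyl cyclase gene ADCY1 was at least 3.78-fold lower and BDH2 at least 3.47-fold lower. BEGAIN was 3.18-fold lower, a plain ratio to its own signal of 12.4 without Dox, which was not well above background. The brighter signals of these 6 genes lay between 33.0 and 68.2, close to the detection limit, and normexp background correction left 1 gene at least 2-fold higher and 0 lower.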

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

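The 75th percentile over all probes and the removal of the GC and gene span trends were chosen after the data were seen. No paired analysis was possible because each condition had 1 array, and for the same reason no array could be left out. Of 30 named genes at least 2-fold apart, all 316 values under the alternatives kept their sign, which their size and the use of the same arrays made likely. Of 1742 values of all 163 named genes, 82 moved by more than the spread between probes. Median scaling and the all-probe percentile move every gene alike and cannot move a list's shift, so they are left out of the following counts. Of 134 shifts of the 15 lists that stood apart, 121 kept direction and stood apart. YAP/TEAD targets (0.31 to 0.36), ribosome biogenesis (0.34 to 0.39) and interferon-stimulated genes (−0.34 to −0.19) did so under each of these 9 alternatives. So did the lists of nuclear-encoded oxidative phosphorylation, ATF4 targets, cytosolic heat shock proteins, replication-dependent histones, proteasome, and lysosome and autophagy. Of 187 shifts of the other lists, 13 came to stand apart. Immediate early genes did so at 0.15 with normexp, 0.16 with quantile normalization, 0.13 with no filter, 0.20 with the stricter filter, 0.16 in the value table, 0.16 with the GC trend and 0.24 with the span trend removed. MHC class I presentation did so at −0.13 (quantile), −0.14 (value table) and −0.15 (GC), mitochondrial ribosomal proteins at 0.079 (GC) and 0.097 (span), and ERK feedback genes at 0.17 (span). Signal over background limits dim genes. Normexp, which adds 50 to each signal and so pulls dim signals together, gave 17 genes at least 2-fold higher and 32 lower, 1 and 0 genes by bound in the genes detected on 1 array (41 and 66 after quantile normalization, against 53 and 46), and 1.12 for SAMD4A. The stricter filter tested fewer genes (9513) and gave 18 higher and 35 lower, −0.93 for SAMD4B, which was also the value of its brightest probe, −0.073 for the matrix list and 0.24 for the angiogenic list, which was reversed; no SAMD4A probe passed it. With no filter, 95 genes were higher, SAMD4A was 1.39, metallothioneins were at −0.0064 and angiogenic factors at 0.0000, since undetected members were set to a floor. The brightest SAMD4A probe gave 3.67. Thresholds of 1.5-fold and 3-fold gave 348 and 11 genes higher, and 827 and 9 lower. Under quantile normalization, loess and the value table, mitochondrially encoded transcripts were at −0.086, −0.105 and −0.084, and cytosolic ribosomal proteins at −0.0198, −0.0324 and −0.018, the latter also at −0.0343 with the span trend removed, none of them apart. Blood cell markers were at −0.41 under quantile normalization and in the value table, no longer apart. For these lists the cause was not tested.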

Other observations

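The tests of the zinc-finger genes and of the genes beside the chromosome 19 run, and the removal of the GC and gene span trends, were chosen after the results were seen. Several metabolic and damage-response lists did not stand apart as groups but held genes with sizeable differences. H1299 cells lack functional p53, and the p53 target list had a median of 0.02 over 23 genes (percentile 60.8). GADD45A (0.92) and AEN (0.79) were nonetheless higher without Dox, while the pro-apoptotic gene BBC3 (−0.72) and FDXR (−0.70) were lower. Glycolysis genes had a median of 0.03 over 22 genes (percentile 90.8), with PFKFB3 (0.66) and HK2 (0.62) highest and PFKFB4 (−0.33) and PFKL (−0.25) lowest. Hypoxia targets had a median of 0.06 over 19 genes (percentile 73.8), with ADM at 1.66 and ANKRD37 at 0.53 against NDRG1 at −0.69 and MXI1 at −0.33. NRF2 targets were at 0.07 over 18 genes (percentile 87.8), from PIR (−0.37) and NQO1 (−0.31) to ME1 (0.46) and SLC7A11 (0.55).

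Lipid genes were mixed. Cholesterol biosynthesis had a median of −0.02 over 24 genes (percentile 34.8), from TM7SF2 (−0.54) and HMGCS1 (−0.39) to CYP51A1 (0.22) and ACAT2 (0.31). Fatty acid synthesis had a median of 0.12 over 14 genes (percentile 90.7), with ME1 (0.46) and GPAM (0.26) highest and FADS2 (−0.68) and ACSS2 (−0.44) lowest. Epithelial genes had a median of 0.04 over 14 genes (percentile 72.2), with CLDN1 (0.50) and KRT18 (0.27) above and CLDN3 (−0.61) and JUP (−0.57) below. Housekeeping reference genes had a median of −0.03 over 15 genes (percentile 65.1). B2M (−0.16) and RPLP0 (−0.13) were lowest, and the transferrin receptor gene TFRC (0.49) was highest. Markers of other cell types were few and dim. Blood cell markers had a median of −0.45 over 7 of 16 genes (percentile 1.66), from CD3D (−0.80) and TYROBP (−0.76) to PTPRC (−0.13) and CD14 (0.30). Endothelial markers were at −0.28 over 5 of 12 genes (percentile 11.4), with ESAM (−0.68), ROBO4 (−0.60), CDH5 (0.01) and VWF (0.17). Fibroblast markers were at −0.39 over 5 of 12 genes (percentile 5.17), with DCN (−0.84), ACTA2 (−0.46), S100A4 (−0.33) and PDGFRB (0.20). Of 5160 measured probes without a gene symbol, 71 were at least 2-fold higher and 28 at least 2-fold lower. Protein-coding genes leaned the other way, with 47 higher and 116 lower, but were counted by gene and not by probe.

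YAP/TEAD targets had a shift of 0.35 from all genes. The probe GC content trend and the gene span trend were argued against, since the shift was 0.34 with either removed and still stood apart. Beside the list, and named after their values were seen, TEAD1 stood at 0.91, YAP1 at 0.22 and WWTR1 at 0.12. VGLL4, which competes with YAP for TEAD, stood at −1.32 and was named because it was among the lowest genes. The other TEAD and VGLL genes are not reported here. These values were picked from the same arrays and give no independent support for a change in TEAD output. A hypothesis is that SAMD4A expression may raise TEAD output. Dox itself or another difference between the cultures, such as cell density, cannot be told apart from this with 1 array per condition and no array of Dox-treated cells without the module.

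Interferon-stimulated genes had a shift of −0.34, or −0.19 over 41 genes with no filter on dim probes. With the probe GC content trend removed it was −0.32, and with the gene span trend removed −0.30, and it stood apart in both, which argues against either trend as the whole source. SAMD4A expression may lower the resting interferon signature of these cells, as a hypothesis. Dox itself or another difference between the cultures cannot be told apart from it, again because there was 1 array per condition and no Dox-treated array without the module.

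On chromosome 19, 6 neighbouring measured genes were all at least 1.5-fold higher without Dox, LYPD5 (1.11), ZNF283 (1.09), ZNF404 (1.42), LOC100505715 (1.22), ZNF45 (1.31) and ZNF221 (0.87), over 145 kb (GRCh37, 44326257 to 44471466). The next longest run among 14766 ordered genes had 3, and chance clustering was argued against, since 0 of 1000 shuffles of the differences gave a run as long and the longest had 5. Sequence shared between the probes themselves was argued against by a best ungapped match of 28 of 60 bases between probes of different genes. Whether a probe also binds the transcript of a related zinc-finger gene was not tested. A response of zinc-finger genes as a family by 1.5-fold or more was argued against by the 235 others on the chromosome. These had a median of 0.12 and an SD of 0.30. A smaller rise of the family stays open, as the median of all measured genes was −0.02. A response of some of them also stays open, as 11 (4.68%, against 2.36% of all ordered genes) were at least 1.5-fold higher. The 5 genes on each side had a median of 0.33. On the left they were mixed, from KCNN4 (−0.56), next to the run, to CADM4 (0.65). On the right, the measured genes from ZNF155 (0.37) to ZNF234 (0.59) were all zinc-finger genes. All of these were higher, the least being ZNF223 (0.14). A local effect, possibly at the site of the inserted module, is a hypothesis. These data leave it open because the site of insertion is not known here.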
